A study of Homo sapiens with 2 samples.

How the data were processed

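Gene expression was measured in SW480 colon cancer cells and in SW480-R cells with acquired resistance to the HSP90 inhibitor 17-AAG, with 1 array for each. Per the labels' protocols, resistant cells were selected by stepwise increases in drug from 1 to 2, 4 and 6 times the IC50 and beyond, with medium changed every 48 h and passage at 80% confluence. Per the labels' protocols, RNA was extracted with TRIZOL, amplified and labelled with the GeneChip 3-prime IVT Express kit and hybridised to the PrimeView human array. That kit primes from the poly-A tail, so probe sets read mainly the 3-prime ends of transcripts.

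The deposited log2 values were made by RMA, per the submitters' processing notes, which give no version. RMA subtracts background, sets the arrays to a common distribution and summarises the probes of a set. The number of arrays normalised together and the software are not given in the sources used here. A common distribution can move other genes up on an array on which abundant transcripts are lost, so the added spike-in controls were followed as a second scale. Whether this happened here was not tested. The deposited values differed in spread, with interquartile ranges over probe sets of 2.69 on the parental and 2.33 on the resistant array. The authors deposited the ratio of parental over resistant signal as a linear fold beside the log2 values, and this ratio equals the log2 difference raised from base 2. The authors also deposited the probe sets at 2-fold and 3-fold as separate tables. A second deposited table of the same log2 values holds 49395 probe sets, of which 102 are controls. It differed from the first by at most 0.234 on the parental and 0.276 on the resistant array. Its medians were 4.91 and 5.07.

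Gene symbols came from the annotation of 2012 in the files and were updated through a reference gene table of GRCh38.p14, which was used for names only. Of 49293 probe sets, 46328 named 1 gene, 2476 several and 489 none, and 99.5% of those naming 1 gene matched. No gene was named from a probe set of several genes. The genome build is not given in the sources used here, so positions are given only as chromosome arms.

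A gene was represented by the probe set with the highest mean log2 value over both arrays. A gene passed the dim filter, and is called bright, when its brighter array was at or above that array's median over all non-control probe sets; 13788 of 18623 genes passed. The difference was resistant minus parental, and counts used a 2-fold threshold. With 1 array per group there was no test. The gauges of measurement error were the spike-in controls (SD 0.25 of the difference over 45 probe sets) and the probe sets of one gene, whose differences had an SD of 1.11 over 7283 genes with 21859 probe sets. These cover neither culture nor RNA preparation.

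A gene list was described by the percentile of its median among 10000 random lists of the same size, matched on mean log2 value in 20 bins, and called when it fell outside the central 95%. Lists needed at least 5 bright members. The 32 lists covered the heat shock response, HSP90 and cochaperones, HSP90 clients, ABC transporters, quinone reductases and NRF2 targets, drug-metabolising enzymes, mesenchymal, epithelial and intestinal genes, Wnt targets, S-phase, G2/M, CDK inhibitors, apoptosis, interferon, antigen presentation, NF-kB, cholesterol, hypoxia, stress responses, proteasome, autophagy, growth factor signalling, oxidative phosphorylation, ribosomal proteins, cancer-testis antigens and markers of 6 other cell types. Chromosome arms with at least 20 genes and the annotation terms of the files with 20 to 200 genes were treated alike.

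The genes named were fixed by rule before the data were examined. They were the 15 genes with the largest positive and the 15 with the largest negative difference among bright genes whose bright probe sets all had the same sign, up to 4 bright members per list with the largest absolute difference, and a fixed set of drug response genes. Genes without an official symbol and families measured only by cross-hybridising sets were left out of the first part. Some genes that the rule names are not reported here. The lists, the rule, the filter and most alternatives were also fixed before the data were examined. The alternatives were other dim filters, median and loess centring (span 0.3), the median over probe sets, leaving out the shared probe sets (those ending in _x_at or _s_at), the second deposited table and other fold thresholds. Centring on the spike-ins, the probe set with the highest parental value and random lists matched on the parental value were added after seeing the data.

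The steps were tested on simulated data for the comparison of resistant with parental, with 200 of 13788 genes changed. At a log2 change of 1.5 up or down 96.0% and 94.0% of changed genes were called, and at 3 up or down all were (100.0%), against 0.0221% of unchanged genes. The simulated noise for these genes had only the spread of spike-in differences, with no offset between the arrays. The measured arrays had a spike-in shift of 0.71 and an SD of 1.11 between probe sets of one gene. The 0.0221% follows from that setting and does not give the share of false calls on the measured arrays. Of unchanged lists of 30 genes 4.0% were called, of lists shifted by 0.5 up or down 82.0% and 42.0%, and of lists shifted by 1 up or down 98.0% and 100.0%. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.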

Results

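The study compared SW480, an established human colon adenocarcinoma line, with SW480-R, a derivative selected for acquired resistance to 17-AAG, a benzoquinone ansamycin that binds the ATP pocket of the chaperone HSP90. The question addressed was which transcripts differ between the sensitive line and the line that survived stepwise exposure to the drug. Total RNA of each line was hybridised to 1 Affymetrix PrimeView array, so the set held 1 parental and 1 resistant array. The resistant cells had been taken through exposures of 1, 2, 4 and 6 times the IC50 and then kept without drug for at least 2 weeks. Each array gave log2 values for 49293 probe sets, with a median of 4.91 on the parental array and 5.08 on the array labelled resistant. With 1 array per group no difference below has a replicate check, and no test, standard error or p-value for the conditions was computed; the number of arrays limits the precision. Percentiles among random gene lists and intervals over genes describe these 2 arrays only. All differences are log2 values, resistant minus parental.

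A part of the transcripts abundant in the parental line was far lower on the array labelled resistant. Of 404 genes at 10 or more on the parental array, 112 (27.7%) were at least 16-fold lower, while 153 (37.9%) stayed within 1 of the shift of the added control RNAs. The mitochondrially encoded ND4, a subunit of respiratory complex I, was at 13.49 on the parental array and 3.92 on the resistant array, at least 341-fold lower. A value below the median of its array was taken as a bound. Folds from such values are set against that median, and log2 differences from them have no exact size or rank. The folds of NQO1, RPS3 and TXN given below rest on resistant values just above that median. Some control probe sets without a target were as high on that array, for example at 5.58, so these folds may also be bounds. LDHB, a lactate dehydrogenase subunit, was at least 92.3-fold lower, EIF4H, a translation initiation factor, at least 101-fold, and FTH1, the ferritin heavy chain, at least 143-fold. Other bright probe sets of EIF4H and FTH1 differed by -3.81 and -3.45. MYC, the growth-promoting transcription factor driven by Wnt signalling in colon cancer, was at 10.76 and 3.99, at least 51.6-fold lower. In the other direction the log2 differences reached 2.37, for the GABA receptor subunit GABRP, which was dim on the parental array and at least 1.91-fold higher.

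Of 13788 genes with a signal at or above the array median on the brighter array, 3336 (24.2%) were at least 2-fold higher and 2539 (18.4%) at least 2-fold lower on the array labelled resistant. At 4-fold, 18 genes were higher and 1417 lower, and at 16-fold 342 genes were lower. The split depended on the scale, because all 45 external spike-in control probe sets, RNAs added during labelling and hybridisation, were themselves higher on the resistant array, by a median of 0.71 (SD 0.25 over probe sets). The 3 trp sets among them were at background level, and the other 42 also had a median of 0.71. Relative to the spike-ins 170 genes were at least 2-fold higher and 3756 at least 2-fold lower, and higher genes made up 4.33% of the calls against 56.8% on the deposited scale. They made up 42.3% when each array was centred on its median and 15.6% after loess centring. The median over all genes was 0.57 on the deposited scale and -0.15 on the spike-in scale. Positive values under about 0.71 therefore change sign on the spike-in scale. That scale subtracts 1 constant from all genes, but the brightest controls shifted less. The cre spike-in sets, at 13.35 to 13.97 on the parental array, differed by only 0.07 to 0.24. For genes of such signal the constant may be too large.

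**Figure D1:**
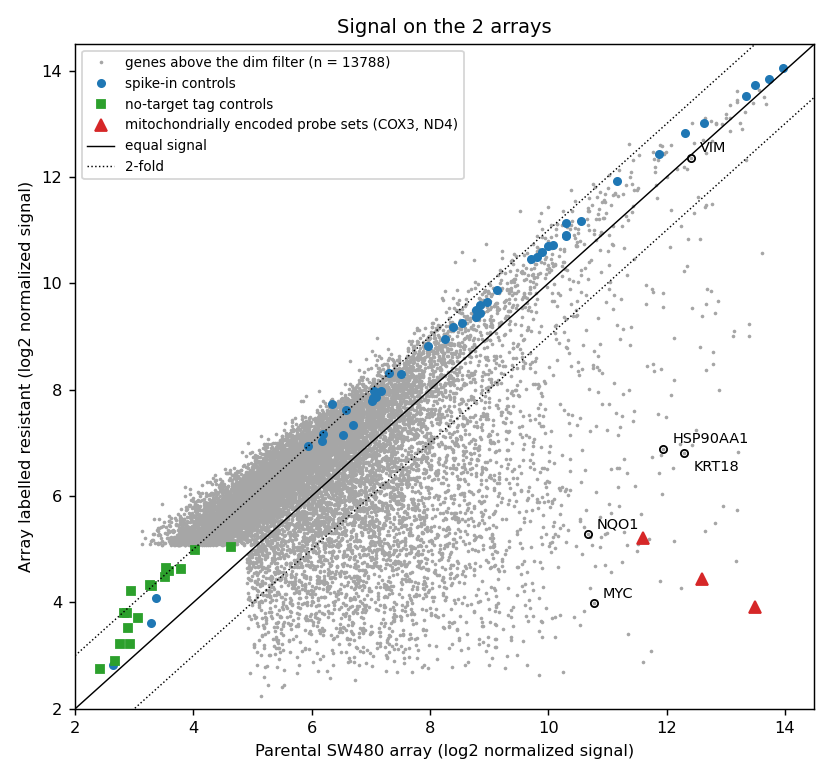
Each grey point is 1 of 13788 genes, with its log2 normalized signal on the parental array (horizontal axis) and on the array labelled resistant (vertical axis); blue, green and red marks are spike-in controls, no-target tag controls and mitochondrially encoded probe sets. The solid line is equal signal and the dotted lines are 2-fold; spike-ins lie above the solid line by a median of 0.71, while ND4, MYC, KRT18, NQO1 and HSP90AA1 lie far below it.

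The 15 genes with the largest lower signal also included COX3, the mitochondrially encoded cytochrome c oxidase subunit (-8.17), and MYL12B, a myosin regulatory light chain (-7.95). PDP1, a phosphatase that activates pyruvate dehydrogenase, differed by -7.57, QPCT, glutaminyl cyclase, by -7.20, GHITM, a mitochondrial inner membrane protein, by -6.96, and SLC5A3, a myo-inositol transporter, by -6.82. RPS3, a protein of the small ribosomal subunit, was 157-fold lower, and the antioxidant protein TXN 125-fold lower. Probe sets of one gene did not always move alike. TGM2, a transglutaminase, differed by -7.49 at its brightest probe set and by -0.58 at another with 8.41 on the parental array. RPL37A, a protein of the large ribosomal subunit, differed by -7.16 at its brightest probe set and by -0.04 at another with 5.07 on the parental array.

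The 15 genes with the largest higher signal were mostly dim on the parental array. GABRP went from 3.48 to 5.85 (2.37), DEFB1, an epithelial antimicrobial peptide, differed by 2.23, ZMYND10, a protein of motile cilia, by 2.20, and CNR1, the cannabinoid receptor of brain, by 2.18. Others were OPTC (2.14), GNRHR (2.14), IGLL3P (2.09), ZNRF4 (2.07), RTP3 (2.06), DOC2B (2.04), RNF144B (2.03), BMP5 (2.03), GRIA4 (2.01) and ISX (2.01). The 17 no-target tag controls, which match no transcript, were also higher, by a median of 0.91.

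Several messages of chaperones, the class to which the drug target belongs, were lower. In the heat shock response list, 9 of 18 bright members were at least 2-fold lower and 2 at least 2-fold higher, with a median of -1.46, below the 0.47 of random gene lists of matched mean signal. DNAJB6, a cochaperone of HSP70, was at 9.16 and 3.82, HSPA13 at 7.11 and 3.14, HSPA4 at 8.34 and 4.91, and HSPH1, a nucleotide exchange factor of HSP70, at 8.95 and 6.18. This was the HSPH1 probe set that fell least, and the others differed by -6.74 to -4.02. Another bright HSPA13 probe set was at -0.35. The transcription factors HSF1 and HSF2, which drive the heat shock response, differed by 0.74 each, equal to 0.03 and 0.04 on the spike-in scale, with another HSF2 probe set at -2.33. HSPB1, a small heat shock protein, was at 10.30 and 9.32. HSPA1A and HSPA8 were not measured by a probe set of a single gene.

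HSP90AA1, the stress-inducible HSP90 isoform, was at 11.94 and 6.89, 33.2-fold lower, with its other bright probe set at -3.26. HSP90AB1, the constitutive isoform, was at 10.61 and 10.28. Of 17 bright members of the HSP90 family and cochaperone list, 7 were at least 2-fold lower and 0 at least 2-fold higher, among them CHORDC1 (-3.62), NUDC (-2.76) and SUGT1 (7.78 and 5.77 on the 2 arrays). The list median of -0.86 lay below that of matched random lists (percentile 0.745), but not below lists matched on the parental signal alone (percentile 20.2). AHSA1, which activates the ATPase of HSP90, differed by 0.20, or -0.51 on the spike-in scale, with probe sets from -1.58 to 0.20.

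The kinases and factors that depend on HSP90 did not stand apart as a list, with 5 of 29 bright members at least 2-fold higher, 6 at least 2-fold lower and a median of 0.26 (percentile 21.3). After centring on the spike-ins 0 were higher, 10 were lower and the median was -0.45. AXL, a receptor tyrosine kinase, was at 8.96 and 4.17, YES1, a SRC-family kinase, at 7.15 and 3.19, CDK6 differed by -1.75 and AURKB by -1.71, while other bright probe sets of AXL and CDK6 were at 0.23 and 1.04. MET, the hepatocyte growth factor receptor, was higher by 1.39 and by 0.68 on the spike-in scale at its only bright probe set. That set was near the array median on the parental array (4.99). The other MET probe sets were dim on both arrays and differed by -0.06 to 0.81. EGFR differed by -0.43 and AKT1 by 0.30, with other bright probe sets of EGFR up to 0.81 and of AKT1 from -2.36 to 1.11, and on the spike-in scale AKT1 was at -0.40.

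NQO1, the quinone reductase that converts 17-AAG to its more potent hydroquinone, was at 10.67 on the parental array and 5.30 on the resistant array, 41.4-fold lower, and its other probe set differed by -2.83. In the list of quinone reductases and NRF2 targets, 12 of 25 bright members were at least 2-fold lower and 2 at least 2-fold higher, with a median of -0.96. The largest differences besides NQO1 were those of FTH1 (-7.96), TXN (-6.97) and FTL, the ferritin light chain (-5.47, with its other probe sets down to -10.08). The list lay below random lists matched on mean signal (percentile 0.06) and inside those matched on parental signal (percentile 6.79). Drug-metabolising enzymes went both ways, with 5 of 32 at least 2-fold higher, 6 at least 2-fold lower and a median of 0.45 (percentile 22.8). Relative to the spike-ins 1 was higher, 8 were lower and the median was -0.23. Lower members were ALDH1A3, a retinaldehyde dehydrogenase (-4.98), GSTP1, a glutathione transferase (-4.03), CYP24A1, the vitamin D hydroxylase (-3.08), and GSTK1 (-2.84). The other GSTK1 probe sets, dim on the parental array, were at 0.69 and 1.18. Another bright GSTP1 probe set, at 5.26 on the parental array, was at 0.50, and other ALDH1A3 sets were at -2.63 to -1.06.

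Among ABC drug efflux transporters, 4 of 13 bright members were at least 2-fold higher and 1 at least 2-fold lower, with a median of 0.91 (percentile 89.0). On the spike-in scale 0 were higher, 2 were lower and the median was 0.20. The efflux pump ABCB1 (P-glycoprotein) was at 7.35 and 8.29, a difference of 0.23 on the spike-in scale. ABCC1 was at 7.19 and 4.42 at its only bright probe set, one shared between transcripts, and its other probe sets were dim on both arrays. ABCG2 was dim on both arrays (4.15 and 4.85). MVP, the major vault protein, was higher by 1.30, ABCC2 by 1.29 and ABCC11 by 1.25, or by 0.59, 0.58 and 0.54 on the spike-in scale.

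Many cell cycle genes were lower. In the G2/M and mitosis list, 22 of 29 bright members were at least 2-fold lower and 0 at least 2-fold higher, with a median of -2.26, below every one of the random lists of either matching (percentile 0.0). TPX2, a spindle assembly factor, was at 8.84 and 3.21, BUB1, a spindle checkpoint kinase, differed by -4.20, TTK, another checkpoint kinase, by -4.01 and KIF20A, a mitotic kinesin, by -3.94. In the S-phase and DNA replication list 18 of 34 were at least 2-fold lower and 2 higher, with a median of -1.04 (percentile 0.0, or 0.68 with parental matching). PCNA, the replication clamp, was at 9.91 and 4.30, RRM2, a ribonucleotide reductase subunit, at 9.86 and 4.77, UHRF1 at 8.02 and 3.80, with another bright probe set 1.27 higher, and RFC4, a clamp loader subunit, at 9.08 and 4.68, with its other probe sets below the median of both arrays.

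CDK inhibitors and p53 targets did not stand apart (3 of 27 higher, 6 lower, median 0.36, percentile 24.0). CDKN1B, which encodes p27, differed by -3.76, RRM2B by -3.16, XPC, a nucleotide excision repair factor, by -2.74 and CDKN2B by 1.72, reversing to -0.82 with the median over probe sets, all of them near or below the array medians. Another bright RRM2B probe set, near the medians of both arrays, was at 0.05. CDKN1A, which encodes p21, was at 8.20 and 7.55, with another bright probe set at 0.36. On the spike-in scale 1 of the list was higher, 10 were lower and the median was -0.35. Apoptosis regulators likewise lay inside the random range (2 of 27 higher, 6 lower, median 0.08, percentile 6.66; 0 higher and 12 lower on the spike-in scale), with XIAP, a caspase inhibitor, at 7.24 and 3.16, PMAIP1 at -2.88 and BIRC2 at -1.56.

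The largest list differences belonged to abundant housekeeping messages. Of 36 bright oxidative phosphorylation genes, 30 were at least 2-fold lower and 0 at least 2-fold higher, with a median of -2.67, which lay below random lists of either matching (percentile 0.0 and 0.47). COX7C was at 10.43 and 3.73, COX6C at 10.71 and 4.28, ATP5PO, an ATP synthase subunit, at 10.70 and 5.23 and ATP5PB at 10.60 and 3.83, its unshared probe set lying below the median of both arrays. Of 34 cytosolic ribosomal protein genes 27 were at least 2-fold lower and 0 higher, with a median of -2.89 (percentile 0.0, or 2.92 and not called with parental matching). RPL32 was at 13.21 and 6.83, RPL7 at 10.96 and 4.70 and RPL6 at 12.23 and 6.97. Another bright RPL32 probe set, at 5.70 on the parental array, was at -0.42. Of 30 proteasome subunits 13 were at least 2-fold lower and 0 higher, with a median of -0.65 (percentile 0.37, or 85.8 and not called with parental matching), led by PSMB1 (-5.39), PSMC2 (-3.93), PSMC6 (-3.77) and PSMA4 (-3.39), and the call was lost with the median over probe sets.

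These lower values stood beside differences in the array's own control probe sets. The 3-prime control probe set of ACTB, which encodes beta-actin, differed by -3.53, while its middle set differed by -0.03 and its 5-prime set by -0.05. For GAPDH the values were -3.88, -0.76 and -1.41. Poly-A spike-ins showed no such gradient, with 3-prime minus 5-prime differences from -0.26 to 0.28. The Alu repeat probe set was at 13.09 and 11.11.

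**Figure D2:**
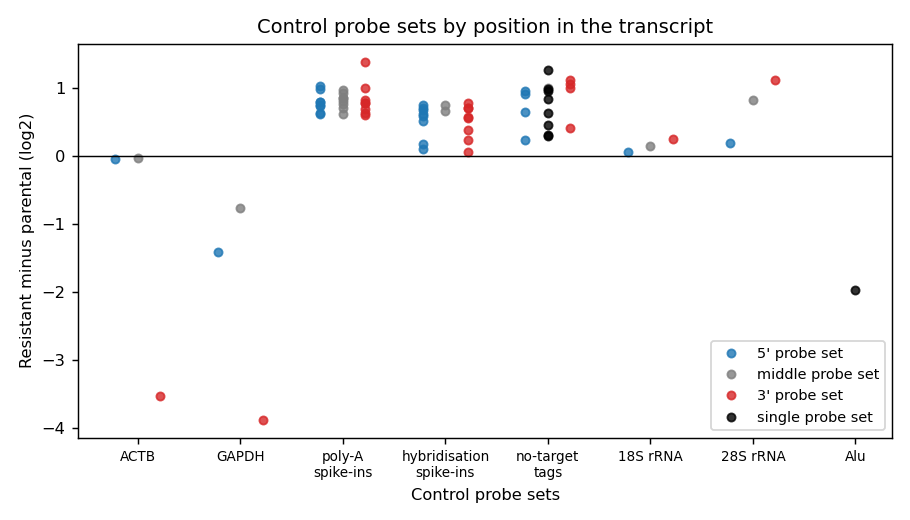
Each point is 1 control probe set, placed by its log2 difference, resistant minus parental (vertical axis), and coloured by its position in the transcript. The 3-prime sets of ACTB and GAPDH lie at -3.53 and -3.88, while all spike-in and no-target tag sets lie above 0.

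In epithelial junction genes, 5 of 31 bright members were at least 2-fold higher and 8 at least 2-fold lower, with a median of 0.16 (percentile 7.52). Spike-in centring gave 0 higher and 9 lower members, and the median was -0.54. KRT18 and KRT8, the keratin pair of simple epithelia, were at 12.30 and 6.80 and at 11.32 and 6.43, SPINT2, a protease inhibitor, differed by -5.26 and EPCAM, the epithelial adhesion molecule, by -4.33. CDH1, which encodes E-cadherin, was at 4.98 and 4.42. Mesenchymal genes gave 7 of 29 higher and 5 lower, with a median of 0.44 (percentile 37.7), or 1 higher, 8 lower and a median of -0.27 on the spike-in scale. CDH11, a mesenchymal cadherin, differed by -5.06, S100A4 by -4.13 and PMP22 by -1.93. VIM, the mesenchymal intermediate filament vimentin, was at 12.41 and 12.36.

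Intestinal differentiation was the one list called higher, with 8 of 22 bright members at least 2-fold higher, 0 at least 2-fold lower and a median of 0.91 (percentile 97.8). Spike-in centring left 19 bright members, of which 0 were higher and 1 lower, and the median was 0.22. ANPEP, a brush border peptidase, was higher by 1.49, and the intestinal transcription factors KLF4 and HNF4A by 1.26 and 1.23. ANPEP was dim on the parental array (4.21), and its other probe set, dim on both arrays, was at 0.26. Another bright KLF4 probe set was at 0.29. The call was lost after loess centring, with the second deposited table and with parental matching. Of 27 Wnt targets and stem cell markers 9 were at least 2-fold lower and 1 higher, with a median of -0.42. The list was called against random lists matched on mean signal (percentile 0.5) and not with parental matching (percentile 8.38). Besides MYC, APCDD1 (-6.51), SOX9 (-5.53) and AXIN2 (-5.00), a feedback inhibitor of the pathway, were lower; other bright AXIN2 probe sets were at -2.44 and -0.36.

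The stress response, glycolysis and cholesterol lists were lower against lists matched on mean signal, and none of them against lists matched on parental signal. In the unfolded protein and integrated stress response list 14 of 31 were at least 2-fold lower and 3 higher (median -0.54, percentile 0.1), with ASNS, asparagine synthetase, at 10.74 and 5.08, the chaperone CANX at -5.02, the transcription factor ATF4 at -4.29 and PDIA6 at -3.24, while other bright CANX probe sets were at -0.38 and -0.26; the call was lost with the median over probe sets. In hypoxia and glycolysis 13 of 30 were lower and 4 higher (median -0.63, percentile 0.08), with LDHA at 11.88 and 6.43, the lactate exporter SLC16A3 at -2.98 (another bright probe set at -0.19), GAPDH at -2.90 and P4HA1 at -2.23; without shared probe sets the median was 0.06 and the call was lost. Cholesterol biosynthesis had 4 of 21 lower and 2 higher (median -0.39, percentile 1.48), with IDI1 at -1.82, EBP at -1.49 and SC5D at -1.24, and its call was lost with the 75th percentile filter. On the spike-in scale 0 cholesterol genes were higher and 11 lower. The stress response list had 0 higher and 19 lower on that scale, and hypoxia and glycolysis 0 and 16. Autophagy and lysosome genes were not called (9 of 31 lower, 2 higher, median 0.03, percentile 7.70), with MAP1LC3B at -4.63, LAMP2 at -4.40 (another bright probe set at -0.06) and GLA at -2.18. Spike-in centring gave 0 higher and 15 lower autophagy and lysosome genes, with a median of -0.68.

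Signalling and immune lists were not called. On the spike-in scale growth factor signalling had 0 members higher and 9 lower, interferon 0 and 5, antigen presentation 0 and 7, and NF-kB 1 and 2. Growth factor ligands and RAS/MAPK feedback genes had 5 of 23 higher and 9 lower (median 0.29), with IER3 at -5.65, DUSP6, an ERK phosphatase, at -4.03 and DUSP4 at -2.79. Type I interferon genes had 5 of 22 higher and 4 lower (median 0.60, percentile 59.0), with the antiviral membrane proteins IFITM1, IFITM3 and IFITM2 at -2.96, -2.64 and -2.15 and BST2 at -2.22. Antigen presentation had 2 of 22 higher and 4 lower (median 0.32, percentile 36.4), with B2M, the light chain of MHC class I, at 11.34 and 5.08, PSMB9 at -1.41, HLA-B at -1.31 and CIITA at 1.33. With the probe set of the highest parental value the antigen presentation median was -0.66. NF-kB and inflammatory mediators had 7 of 22 higher and 2 lower (median 0.67, percentile 77.5), with SAA1 at -4.68, NFKB1 at -1.73, IL1B at 1.85 and IL11 at 1.49.

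Markers of other cell types lay inside the random range. The medians were 1.20 for 5 cancer-testis antigens, 1.04 for 7 fibroblast, 0.89 for 8 leukocyte, 0.96 for 9 endothelial, 1.08 for 10 squamous, 0.60 for 11 neuroendocrine and neuronal and 1.01 for 8 hepatocyte markers. On the spike-in scale these medians lay between -0.07 and 0.50. COL1A1, a fibrillar collagen chain, was at 5.82 and 7.79, COL3A1 differed by 1.71, the cancer-testis antigen CTAG2 by 1.57, the macrophage marker CD68 by 1.15, PECAM1 by 1.28, ALB by 1.40 and SYT1 by -1.91. KRT5, a keratin of basal and squamous epithelium, was at 11.29 and 6.69. Of all 32 lists, 13 were called, 12 of them lower and 1 higher, where 1.6 would be called by chance. With random lists matched on the parental signal 4 were called, all of them among the 13, namely heat shock, S-phase, G2/M and oxidative phosphorylation.

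**Figure D3:**
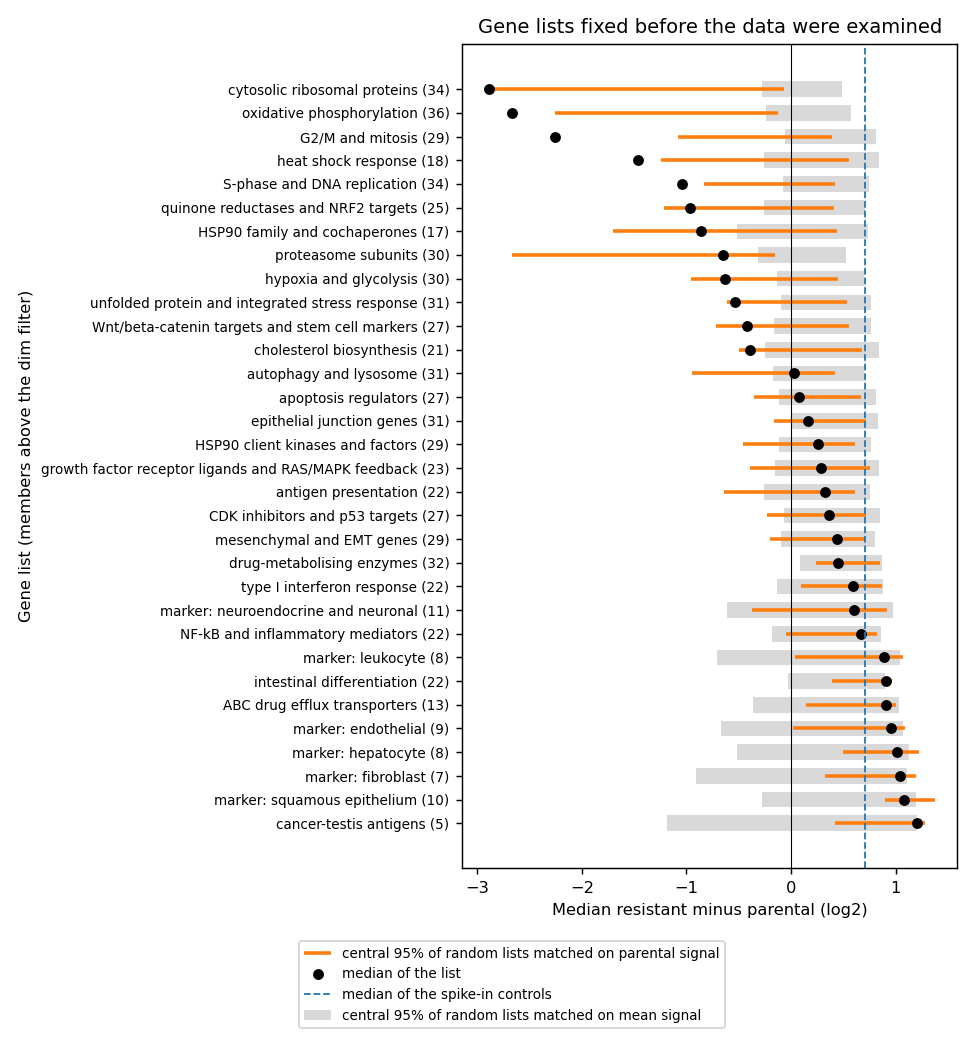
Black points are the median log2 differences, resistant minus parental (horizontal axis), of the 32 gene lists, with the number of bright members in parentheses. Grey bars and orange lines are the central 95% of 10000 random lists matched on mean signal and on parental signal, and the dashed line is the spike-in median of 0.71; ribosomal protein, oxidative phosphorylation and G2/M lists have the lowest medians (-2.89, -2.67 and -2.26).

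The authors' deposited tables of fold changes list 17583 of 49293 probe sets (35.7%) at 2-fold or more, of which 9747 were higher and 7836 lower on the array labelled resistant. At 3-fold the authors' deposited table lists 6431 probe sets, 845 of them higher and 5586 lower. Recomputing the ratios from the log2 values gave the same probe sets.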

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

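The tests of RNA degradation, of the kept share with the parental choice of probe set, of the split share among genes with a lower probe set, of the normalization offset and of regulation against the no-target controls were chosen only after their results had been seen, and the arm test after the arm medians had been seen. Control probe sets outside the gene comparison showed a signal difference between the arrays. The median difference, resistant minus parental, was 0.61 for 18 hybridisation spike-ins, 0.79 for 24 poly-A spike-ins and 0.91 for 17 no-target tags, with every one of these probe sets higher on the array labelled resistant.

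A part of the abundant mRNAs was far lower on the array labelled resistant. The tables argue against less labelled RNA or a failed hybridisation, since 404 genes at 10 or more on the parental array had an interquartile range of 4.37 in their difference, and against 5-prime degradation, since the 3-prime control sets of ACTB and GAPDH were lower by more than the 5-prime ones (a further -2.47 in GAPDH, the smaller gap). Loss of 3-prime ends throughout is also argued against, because 37.9% of those genes (Wilson 95% interval 33.3 to 42.7) stayed within 1 of the spike-in shift, and 33.5% of 436 genes (29.2 to 38.0) when the probe set was chosen on the parental array alone. RNA of another species than human, or a mislabelled sample of that kind, may be a candidate explanation. Splicing factor genes known for ultraconserved sequence (20 bright) had a median of 0.38. This lay at percentile 99.5 of random lists matched on the parental signal but 73.8 of those matched on mean signal. Of these genes 5 were at least 2-fold lower (SRSF3 by -4.17). The mitochondrially encoded probe sets, all of COX3 or ND4, had a median of -8.17. Both genes are among the 15 with the largest lower signal, so they belong to the pattern itself and are no separate support. The species is not identified by these data, and the Alu probe set at 11.11 was still bright. Regulation of whole genes in resistant cells stays open, since 5.70% of 386 genes with at least 2 probe sets at 9 or more on the parental array (22 genes; interval 3.79 to 8.48), or 11.3% of the 195 of them with a probe set at least 16-fold lower (7.57 to 16.5), had one probe set 16-fold or more lower and another near the spike-in shift, and neither interval lies wholly beyond a bound set for either answer.

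Many genes were at least 2-fold higher on the array labelled resistant. An offset from the normalization stays open as a possible explanation: the spike-ins were higher by a median of 0.71, but the drop from 3336 to 170 genes after centring on them follows from subtracting that constant and is no further evidence. The median of the no-target tags was 0.91, or 74.3% of the median of the genes called higher (1.22), so a rise of 0.91 also occurred without a target. Those genes were chosen for a difference of 1 or more and the tags were not, so the share depends on that threshold. That of 23 GC background probe sets, which also have no target, was 46.7% of it. Sets of low signal lower this second share: those at 2.51 or less on the parental array differed by 0.13 to 0.39. Those from 3.38 to 5.88 on the parental array differed by 0.81 to 0.99, and the brightest, from 6.87 to 10.7, by 0.48 to 0.76. Signal rose with GC content over these sets, so the roles of signal and GC content cannot be told apart. Regulation therefore stays open only for what lies above the rise of sets without a target. Single genes above the offset remain open.

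Genes of 13q and 18p were lower than matched genes, with medians of 0.07 and -0.59 where random lists had 0.63 and 0.59. A copy number change of whole arms could shift all their expressed genes together; over the 264 genes of both arms the shift of the 75th percentile was 37.3% of the shift of the median (24.8 to 49.8), between the bounds set for either answer. No DNA was measured, so this stays open.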

How the results depend on the processing

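The spike-in centring, the probe set with the highest parental value and the parental matching were chosen after seeing the data. No paired analysis was possible because each group had 1 array, and no array could be left out. The count of lower genes lay between 1812 and 3756 over all alternatives run, within 1.5 times of 2539, and signal near background limits what dim genes can show. The cause of the changes below was not tested, except that other thresholds and filters change which genes can be counted. The count of higher genes was 1688 with the 75th percentile filter, 2045 with median centring, 580 with loess, 170 on the spike-in scale, 317 at 3-fold and 6782 at 1.5-fold. List medians on the spike-in scale were -0.23 for drug-metabolising enzymes, -0.27 for mesenchymal, -0.54 for epithelial, 0.22 for intestinal, -0.11 for interferon, 0.0145 for NF-kB, -1.10 for cholesterol, -3.59 for ribosomal proteins, 0.33 for fibroblast, 0.25 for endothelial and 0.37 for squamous genes. With loess they were 0.46 for intestinal, 0.45 for fibroblast, 0.36 for endothelial and 0.52 for squamous genes. With the median over probe sets they were -0.16 for drug-metabolising enzymes, -0.13 for interferon and -1.09 for cholesterol, and with the highest parental probe set -2.43 for Wnt targets, -0.87 for cholesterol and -3.83 for ribosomal proteins. That choice of probe set also made 5 positive list medians negative. They were -0.66 for antigen presentation, -0.67 for apoptosis, -0.32 for CDK inhibitors, -0.24 for growth factor signalling and -0.30 for autophagy. Hypoxia and glycolysis moved to -1.48 and the stress response to -1.11. Of the 13 list calls, cholesterol was lost with the 75th percentile filter, stress response and proteasome with the median over probe sets, and intestinal with loess and the second table. Hypoxia and glycolysis reversed to 0.0601 without shared probe sets. With parental matching 117 annotation terms were called in place of 194, 46 lower and 71 higher against 117 and 77. Genes that reversed were, with the median over probe sets, ABCC1 (0.45), GSTK1 (0.65), RFC4 (0.72) and CDKN2B (-0.82); without shared probe sets, ABCC1 (0.89), HLA-B (0.48) and ATP5PB (0.10); and with the highest parental probe set, CDKN2B (-1.35). The values of RFC4, ABCC1, HLA-B and ATP5PB rest on probe sets below the median of both arrays, where a lower signal could not be measured (0.10 for ATP5PB), so they show no change of direction. The GSTK1 value sets the resistant level of one probe set (5.17) against the parental level of another (4.51). It therefore measures no change of direction either.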

Other observations

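The quartile test of the arms, the spike-in scale and the parental matching were chosen after seeing the data. Of 710 annotation terms, 194 were called, 117 lower and 77 higher, where 35.5 would be called by chance; with parental matching 46 were called lower and 71 higher. The terms named lay farthest from matched random lists in units of their spread, leaving out terms that share most genes with one already named. Lower terms were viral transcription, a term made up mostly of ribosomal protein genes (63 genes, median -2.88), the respiratory electron transport chain (79 genes, -2.36), mRNA metabolic process (197 genes, -0.94), M phase of the mitotic cell cycle (84 genes, -0.94) and rRNA processing (95 genes, -0.68). Higher terms were sensory perception of smell (140 genes, 1.18), where 91 genes, mainly olfactory receptors, were at least 2-fold higher, elevation of cytosolic calcium (65 genes, 1.02), regulation of ion transmembrane transport (101 genes, 0.97), inflammatory response (187 genes, 0.90) and calcium ion transport (100 genes, 0.87). The median of the no-target tags was 0.91.

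Of 41 chromosome arms 15 were called, where 2.05 would be called by chance. Lower arms were 2p (0.29), 3q (0.37), 5q (0.41), 6q (0.53), 7p (0.28), 9q (0.40), 12p (0.40), 13q (0.07) and 18p (-0.59), and higher arms were 1q (0.71), 4p (0.74), 16p (0.68), 19p (0.65), 19q (0.74) and 22q (0.67).

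Probe sets of one gene were far apart in 22 of 386 genes with at least 2 probe sets at 9 or more on the parental array, chosen after their values were seen. CDK4, the G1 kinase, ranged from -4.19 to 0.24, HMGB1, a chromatin protein, from -5.30 to 0.31, PKM, pyruvate kinase, from -5.52 to 0.61, STMN1, a microtubule regulator, from -6.01 to 0.32, and RPL9 from -7.78 to -0.09. Of the 386 genes 195 had a probe set at that level at least 16-fold lower, in 76 of them all probe sets at that level and in 119 only some. No gene was dim on the parental array and at 9 or more on the resistant array, while 115 genes were dim on the resistant array and at 9 or more on the parental array.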
